A study of Peucedanum japonicum with 2 samples.

How the data were processed

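Small RNA was sequenced from exosome-like nanovesicles of leaves of Peucedanum japonicum, a plant of the carrot family. Exosome-like nanovesicles are membrane-bound particles recovered here from plant juice by centrifugation. Per the labels' protocols, shop-bought plants were juiced, the juice was cleared at 3000 x g and 10000 x g, and vesicles were pelleted at 150000 x g and parted on steps of 8, 30, 45 and 60% sucrose. Per the same protocols 2 bands were collected, and the labels do not say which of them was sequenced, nor whether both libraries came from the same band. Libraries were made with a NEBNext small RNA set and sequenced on an Illumina instrument. The protocols name no molecular identifiers, so the intervals, detection limits and exact binomial p-values given here cover counting error only.

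The authors deposited 1 table of raw read counts per mature entry of miRBase, the public catalogue of microRNAs, with 48885 entries of many organisms and 2 columns, called prep3 and prep7 here. Per the submitters' processing notes the tools included Trim Galore 0.6.7, Bowtie and SAMtools. The settings for mismatches, for reads with several equal hits and for read length, and the miRBase release, are not given in the sources used here. These settings decide how freely a read that is not a microRNA can be placed on an entry. Entry names are used as the file gives them. Entry sequences and a genome were not used here, so matches were not checked by sequence and no coordinates are given. A line of the table that names no entry held 0 reads and was left out. The 2 samples form 1 group, and the preparation numbers in the column names match no replicate number of the titles, so both columns were treated as replicates of the group with no order. Nothing says that they came from separate plants, so the spread between these libraries may be technical. No p-value given here takes that spread into account: the binomial and chi-square ones rest on counting error, and the Fisher and permutation ones run over families. The deposited counts summed to 3632255 reads in prep3 and 5514265 in prep7. The limit that a count of 0 allows, 3 counts, was 8.26e-05% and 5.44e-05% of these totals.

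Entries were called plant-named when the number follows miR directly in the name, the form miRBase uses for plants, with some algae included. They were called virus-named by their prefix, and animal-named otherwise, with a few other organisms included. Entries were summed to families by the number in the name, with miR156 and miR157, miR165 and miR166, and miR170 and miR171 merged, because reads of 1 microRNA can fall on near-identical entries of many species. Family abundance is the share of plant-named reads in percent, with mean ± SD over the 2 libraries. A family was called detected with at least 10 reads in both libraries. Shares of a single library carry 95% Wilson intervals. With 1 group of 2 libraries no permutation test across libraries can go below p = 0.5, so families were compared by whether the ranges of their libraries separate. Conserved and other families were compared with a two-sided Fisher's exact test. Reads of each detected family were compared between the libraries with a two-sided exact binomial test given the plant-named totals, with Benjamini-Hochberg adjustment at 0.05. That test compares these libraries, not conditions. On simulated counts for the 1214 detected families it called 67.0% of 100 families changed 2-fold, 24.0% of 100 changed 1.25-fold and 0.296% of 1014 unchanged ones. The simulated counts held counting error only, with no spread between libraries. These rates therefore do not carry over to libraries that differ by more than counting error. Replicate agreement was taken as correlations of log2(RPM + 1) across families, RPM being reads per 1000000 plant-named reads, and as the common dispersion of edgeR 4.0.16 after TMM scaling with an intercept-only design. DESeq2 1.42.0 gave alternative size factors. The remaining steps used R 4.3.3, Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

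The family lists, the tests of the design, the alternative settings and the rule for naming families were fixed before the data were examined. The rule takes the 20 most abundant plant-named families, up to 4 members per list, the 5 families with the largest and the 5 with the smallest ratio between the libraries among those past the threshold, the 5 most abundant animal-named families, and arm shares for the 8 most abundant families with at least 100 arm-labelled reads in both libraries. Families named outside this rule were chosen after their values were seen, and the text says so. The lists covered families that regulate transcription factors and growth, the small RNA pathway, nutrients and copper, and disease resistance genes, families conserved among flowering plants, monocot and moss families, animal markers, and entries suspected of matching fragments of abundant RNA. The suspect animal family miR-6087 of the list has no entry in the table.

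Several parts were added after the counts had been seen. They are the background of 308 animal-named families with at least 20 entries, the 10000 random lists matched on entry number, the comparison restricted to families with at least 10 entries, the comparison of single-entry families, detection by the highest entry of a family, the lists without their top member, the highest members of the random lists, the lists of guide arms and the tests of near-equal entries. Also added were the share of calls kept with TMM scaling, the permutation test of the shift of conserved families, and the test on virus-named entries with a read. Each member of a random list was drawn from the 30 animal-named families nearest in entry number. The alternative settings fixed with the design, ahead of the counts, were other read minimums, other denominators, the highest entry in place of the family sum, unmerged families, other scalings, other pseudocounts, a fold minimum of 1.5, suspect entries left out, and each library left out.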

Results

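The data describe on which miRBase entries the small RNAs of Peucedanum japonicum leaf nanovesicles were placed, in 2 libraries of 1 group with no control. The design is a profile, so comparisons are made between microRNA families, between plant-named entries and those of other organisms, and between the libraries. The prep7 library held 1.52 times the reads of prep3 (5514265 against 3632255). Of the 48885 entries, 62.7% had a read in prep3 and 69.5% in prep7, with a median of 2 and 3 reads per entry. The 100 most abundant entries held 45.1% of reads in prep3 and 43.1% in prep7.

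Plant-named entries took 19.3% ± 1.48 of all reads (SD, n = 2). Their share was 20.3% in prep3 (95% Wilson interval 20.3 to 20.4) and 18.2% in prep7 (18.2 to 18.3). Animal-named entries took 77.4% ± 1.43 and virus-named entries 3.32% ± 0.0450. In the table itself, 21.5% of entries are plant-named, 77.4% animal-named and 1.08% virus-named. Relative to their number of entries, plant-named entries held 0.946 and 0.848 times the average reads in prep3 and prep7, animal-named entries 0.987 and 1.01 times, and virus-named entries 3.03 and 3.09 times.

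Among plant-named families, miR165/miR166, which targets class III HD-ZIP transcription factors of leaf polarity, was the most abundant at 15.7% ± 1.65 of plant-named reads (SD, n = 2, as for all means of this kind). It held 16.9% in prep3 and 14.6% in prep7, and both values lay above those of the other 2939 families in both libraries. This first place rests on summing entries: the highest single entry of miR165/miR166 held 1.16%, against 6.57% for that of miR10407. Single entries compare unevenly if reads of 1 sequence were split over several entries, which was not checked by sequence. Next came miR10407 with 6.57% ± 3.81 and miR2916 with 5.67% ± 4.09. They were followed by miR398, which targets copper/zinc superoxide dismutases, with 4.57% ± 1.21, miR482, which targets disease resistance genes, with 3.59% ± 0.347, and miR396, which targets growth-regulating factors, with 3.22% ± 2.23. The order of these families is not resolved with 2 libraries: miR10407 held 3.88% in prep3 and 9.27% in prep7, and miR2916 held 8.56% and 2.78%. Of the 20 most abundant families, 2 had ranges that separated from the next family in rank, miR165/miR166 and miR12163.

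The rest of the 20 families spanned a narrow range of means. Above 2% lay miR8637 (2.89% ± 0.226), miR5217 (2.69% ± 1.17), miR1445 (2.25% ± 1.56) and miR10199 (2.16% ± 0.813). Between 1 and 2% lay miR530 (1.83% ± 0.223), miR6478 (1.65% ± 1.22), miR1886 (1.45% ± 0.591), miR5514 (1.43% ± 1.16), miR1135 (1.25% ± 0.0417), miR159 (1.24% ± 0.707), miR7749 (1.06% ± 0.341) and miR9657 (1.03% ± 0.794). Lowest were miR12163 (0.920% ± 0.0334) and miR3628 (0.724% ± 0.132). The 10 most abundant families of each library held 50.4% ± 5.23 of plant-named reads.

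Of these 20 families, 5 belong to the list conserved among flowering plants, and 13 drew over 90% of their reads from 1 entry, 8 of them being families with a single entry. The miR10407 reads lay at 99.9% on the soybean entry gma-miR10407c, and all miR2916 reads on the poplar entry peu-miR2916. The miR165/miR166 reads were spread over entries of several species. Taking its 13 entries with at least 0.5 of the highest entry's reads in prep3, counts ran from 5045 to 8866 in prep3 and from 3928 to 11583 in prep7, and they were not equal (chi-square 1461 and 9116). A subset of 11 of them, chosen after the counts were seen as those reaching 0.5 of the highest entry in both libraries, held from 8513 to 8866 reads in prep3 and from 11174 to 11583 in prep7. These 11 held 76.4% and 85.4% of the family and differed by no more than sampling noise allows (chi-square p = 0.356 and 0.282 for equal counts), but selecting them by their similar counts favours that result. Summed, the 11 held 95392 reads in prep3 and 125192 in prep7, more than the 28684 and 93211 of miR10407. The entries left out were ptc-miR166p, with 5045 and 3992 reads, and zma-miR166h-5p, with 8727 and 3928.

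**Figure D1:**
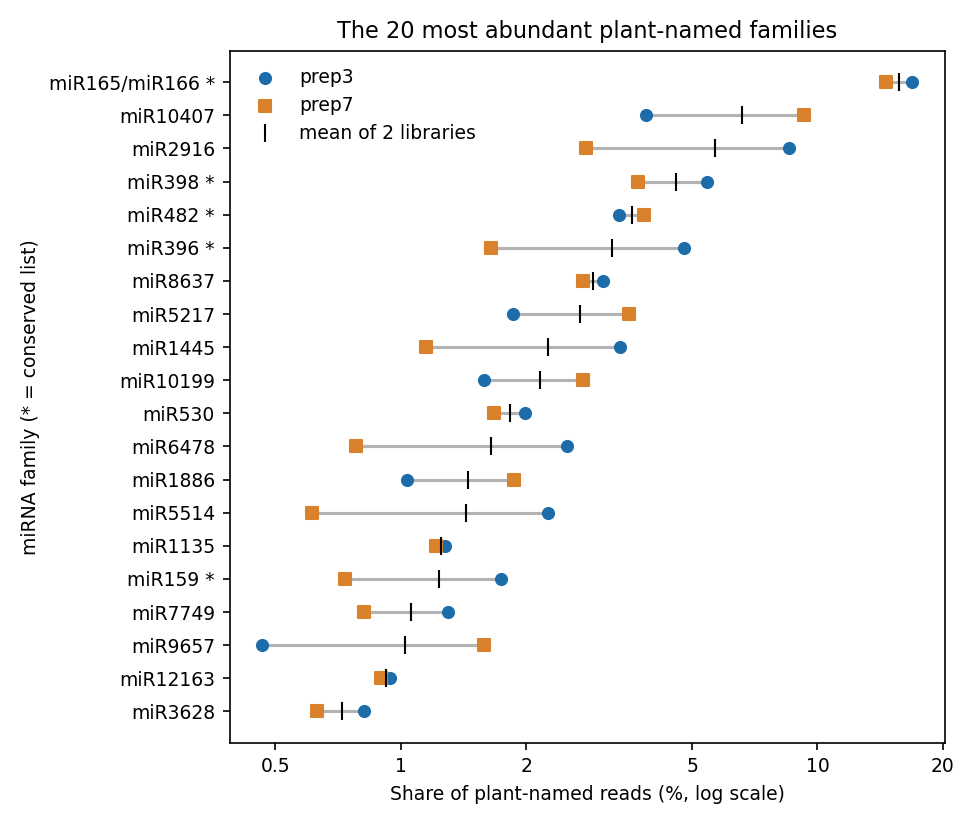
Share of plant-named reads (percent, log axis) of the 20 most abundant plant-named families; circles are prep3, squares prep7, ticks the mean of the 2 libraries and grey lines their range, and asterisks mark the conserved list. Both values of miR165/miR166 (16.9% and 14.6%) lie to the right of all values of the other families.

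Families conserved among flowering plants were detected more often than other plant-named families when all families were counted. Of the 28 conserved families, 27 (96.4%) had at least 10 reads in both libraries, against 1187 of 2912 others (40.8%; two-sided Fisher's exact p = 6.09e-10, odds ratio 39.2; families are not replicates). The conserved family that fell short, named after its value was seen, was miR828, a regulator of MYB genes, with 6 and 42 reads. Together the conserved families held 32.1% ± 5.51 of plant-named reads, and 16.3% ± 3.86 without miR165/miR166. Conserved families hold many more entries than the others, and a comparison added after the data were seen did not pass the threshold: among families with at least 10 entries, 27 of 28 conserved and 52 of 58 others were detected (two-sided Fisher's exact p = 0.419, odds ratio 3.12).

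The 18 families that regulate transcription factors and growth held 23.0% ± 4.50 of plant-named reads, with 17 detected. Their most abundant members were miR165/miR166, miR396, miR159, which targets GAMYB-like genes, and miR172, which targets AP2-like genes of flowering time, with 0.577% ± 0.0555. Without miR165/miR166 the list held 7.27% ± 2.85. Family and list sums count both arms of a microRNA hairpin, not only the guide arm, the strand usually loaded into the silencing complex. In miR172, entries with an arm in their name held 99.7% of reads in prep3 and 99.3% in prep7. On its guide arm lay 0 of 4540 such reads in prep3 and 0.0186% of 5373 in prep7. In miR165/miR166, miR396 and miR159 the guide arm held the majority of such reads in both libraries. All 7 nutrient and copper families were detected and held 4.99% ± 1.19, or 0.417% ± 0.0246 without miR398. The next members were the phosphate family miR399 (0.149% ± 0.0109), the copper family miR408 (0.107% ± 0.0100) and the sulfate family miR395 (0.104% ± 0.0349).

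The 5 disease resistance families were all detected and held 3.85% ± 0.470, or 0.267% ± 0.123 without miR482. After miR482 came miR2118 (0.138% ± 0.0482), miR472 (0.122% ± 0.0705) and miR1507 (0.00466% ± 0.00353). The 3 small RNA pathway families, all detected, held 0.360% ± 0.216, or 0.181% ± 0.164 without miR168. Of these, miR168, which targets AGO1, held 0.179% ± 0.0515, miR162, which targets DCL1, 0.120% ± 0.123, and miR403, which targets AGO2, 0.0616% ± 0.0415. Of 5 monocot families 4 were detected, and the list held 0.0904% ± 0.0118, led by miR444 (0.0384% ± 0.0142). Of 4 moss families 3 were detected, and the list held 0.612% ± 0.0318, led by miR1023 (0.584% ± 0.0274). Of 9 suspect plant families 7 were detected, and the list held 1.94% ± 1.38, led by miR6478.

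All 28 conserved families lay within the range of animal-named families, which were used as an internal background because the series has no control. Among 308 animal-named families with at least 20 entries, 5 of the 28 conserved families lay above the 95th percentile: miR165/miR166 (99.7), miR398, miR482 and miR396 (99.4 each) and miR159 (96.8). Of the 308, 1 held as many reads as miR165/miR166, which had 3.05% of all reads. Further conserved families, chosen after their values were seen, were miR172 at 90.9, miR168 at 72.7 and miR408 at 64.0, and 5 of the 28 lay below the 50th percentile. The median of the list lay at the 71.3rd percentile, within the limits of 50.6 and 79.4 that hold 95% of 10000 matched random animal-named lists. Single-entry families were detected in 30.5% of 1845 plant-named and 42.3% of 4292 animal-named cases (two-sided Fisher's exact p = 1.54e-18, odds ratio 0.598; families are not replicates).

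**Figure D2:**
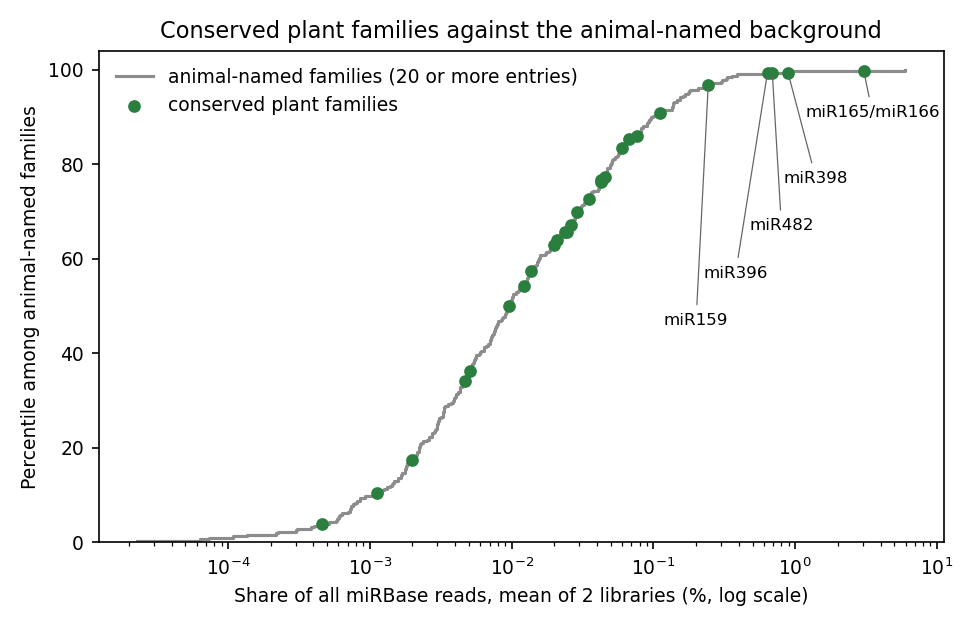
Each green point is a conserved plant family, placed by its share of all miRBase reads (percent, log axis, mean of 2 libraries) and by its percentile among 308 animal-named families with at least 20 entries, whose cumulative distribution is the grey line. The 5 named families lie above the 95th percentile, and the median of the list is at 71.3.

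The most abundant animal-named family was miR-9, with 5.96% ± 1.01 of all reads, of which 99.5% lay on the silkworm entry bmo-miR-9b-3p. It was followed by miR-982 (1.67% ± 0.308), miR-12081 (1.60% ± 0.542), miR-8112 (1.52% ± 1.57) and miR-9819 (1.37% ± 1.08). The 20 marker families of vertebrates, insects and nematodes held 1.92% ± 0.362 of all reads. Their most abundant members were miR-184 (0.910% ± 0.347), miR-92 (0.250% ± 0.114), miR-10 (0.226% ± 0.0633) and miR-21 (0.141% ± 0.0562). Entries suspected of matching fragments of abundant RNA held 0.802% of reads in prep3 (95% Wilson interval 0.792 to 0.811) and 0.234% in prep7 (0.230 to 0.239). Of these, ptc-miR6478 had 18542 and 7875 reads, bta-miR-2478 had 6453 and 1958, gma-miR6300 had 861 and 381, and ppt-miR894 had 982 and 163.

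The guide arm is the strand of a microRNA hairpin usually loaded into the silencing complex. In miR165/miR166 the 3p arm, its guide, held 72.7% ± 6.41 of arm-labelled reads. The 3p arm is also the guide of miR482, where it held 94.9% ± 0.476, of miR159, with 69.8% ± 1.32, and of miR398, with 35.4% ± 6.37. Arm-labelled entries held only 2.96% and 5.63% of the miR398 reads, and from 28.2% to 40.0% of those of miR165/miR166, miR159 and miR396. In miR396, whose guide is 5p, the 3p arm held 41.2% ± 8.51. The 3p share was 99.1% ± 0.191 in miR530, where arm-labelled entries held 7.96% and 6.86% of reads, 0.620% ± 0.303 in miR1886 and 0.0183% ± 0.0258 in miR7749.

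Of 21 conserved families with an assigned guide arm and at least 100 arm-labelled reads in both libraries, the guide arm held the majority in both in 6, namely miR159, miR165/miR166, miR168, miR390, miR396 and miR482, a set known only after the values were seen. It held the minority in both libraries in 12. The conserved family miR858, with 576 and 944 arm-labelled reads, had no guide arm assigned and was left out. Summed over the 21 families, the guide arm held 65.9% of arm-labelled reads in prep3 and 70.3% in prep7, or 43.6% and 31.6% without miR165/miR166 and miR482, left out after their values were seen. Examples chosen after their values were seen are miR172, miR156/miR157 and miR167. In miR172, 0 of 4540 arm-labelled reads in prep3 (95% Wilson upper bound 0.0845%) and 0.0186% of 5373 in prep7 lay on the guide arm. In miR156/miR157, a family of the juvenile phase, it held 5.13% ± 3.12, and in miR167, which targets auxin response factors, 11.6% ± 2.09. Entries with no arm in their name are left out of these shares, and with them counted as guide 14 of the 21 families had a guide majority in both libraries.

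**Figure D3:**
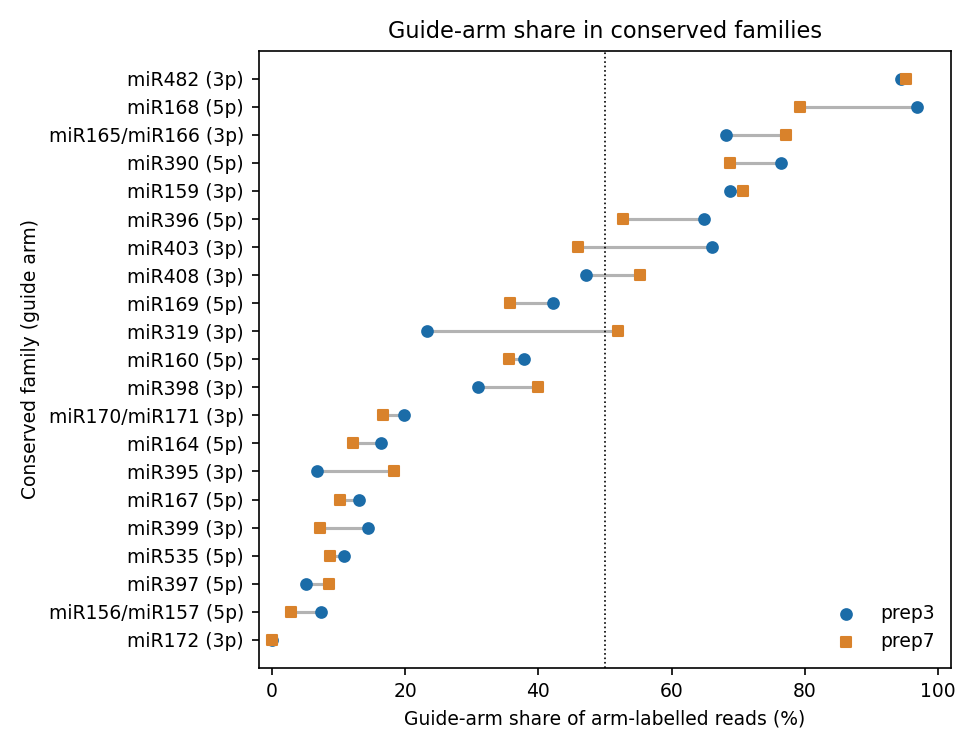
Guide-arm share of arm-labelled reads (percent) in the 21 conserved families with an assigned guide arm and at least 100 such reads in both libraries (miR858 had none assigned); circles are prep3, squares prep7, and the dotted line marks 50%. Both values lie above the line in 6 families and below it in 12, with miR172 close to 0.

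The libraries ranked families alike but differed by more than counting error. The families with the highest ratios of prep7 to prep3 among those past the threshold were miR173, which triggers trans-acting small RNA production in Arabidopsis (log2 ratio 3.95, 57 and 1206 reads), miR8607 (3.94), miR11523 (3.72), miR8776 (3.68) and miR5171 (3.65). Of the miR173 reads, 49.9% lay on the 3p entry aly-miR173b-3p. The lowest ratios were those of miR6028 (-3.14), miR894 (-3.03), miR5473 (-2.65), miR162 (-2.64) and miR3711 (-2.59). By the exact binomial test 691 of the 1214 detected families differed (adjusted p under 0.05), 478 higher and 213 lower in prep7. TMM scaling moved the median log2 ratio from 0.30 to -0.05 and gave 339 higher and 318 lower.

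Among the most abundant families, miR396 (log2 ratio -1.54), miR159 (-1.24), miR398 (-0.55) and miR165/miR166 (-0.21) were lower in prep7 with both scalings, and miR10407 (1.25) was higher with both. Also lower with both were miR5514 (-1.88), miR6478 (-1.68), miR2916 (-1.62), miR1445 (-1.55), miR7749 (-0.67), miR3628 (-0.38), miR530 (-0.25), miR8637 (-0.16), miR12163 (-0.07) and miR1135 (-0.07). Also higher with both were miR9657 (1.77), miR5217 (0.92), miR1886 (0.86) and miR10199 (0.79). The direction of miR482 depended on the scaling, with 0.20 by plant-named totals and -0.15 with TMM. All 3 small RNA pathway families were lower in prep7 with both scalings. Of the 17 transcription factor and growth families tested, 6 were higher and 7 lower (4 and 12 with TMM). Of the 7 nutrient and copper families, 3 were higher and 3 lower (1 and 3 with TMM), and of the 5 disease resistance families 4 were higher and 0 lower (3 and 1 with TMM). Of the 27 conserved families tested, 11 were higher and 13 lower (6 and 18 with TMM). Of the 4 monocot families 3 were higher and 1 lower with either scaling, and of the 3 moss families 2 were higher and 0 lower (1 and 1 with TMM). Of the 7 suspect plant families 5 were lower and 0 higher (7 and 0 with TMM). Adjusted over the list alone, the numbers of calls equalled those over all families tested: 13 for transcription factors and growth, 3 for the small RNA pathway, 6 for nutrients and copper, 4 for disease resistance, 24 for conserved, 4 for monocot, 2 for moss and 5 for suspect plant families.

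Across the 2769 plant-named families with a read, log2(RPM + 1) correlated with Pearson's r = 0.907 and Spearman's rho = 0.879, and families are not independent replicates. The biological coefficient of variation over the 1214 detected families was 0.458. The chi-square of the family counts was 69.7 times its degrees of freedom, so the columns differed by far more than sampling noise.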

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

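Both tests below were chosen after the counts had been seen, and the value of the test on virus-named entries was not yet known when its prediction was written. Reads on entries of organisms other than plants lay far above the limit that a count of 0 allows: animal-named entries took 76.4% of reads in prep3 and 78.4% in prep7, and virus-named entries 3.29% and 3.35%. They stand out because the series profiles a plant and holds no control. The tables argue against RNA of animal origin as the source of most arm-labelled marker reads. Over 17 marker families whose guide arm is well known, 14.4% of these reads lay on that arm in prep3 and 10.6% in prep7. Without miR-184 the shares were 23.5% and 22.4%, and guide arms made up 47.7% of the entries. The 20 marker families held only 1.92% of all reads, so these values do not cover most animal-named reads. By families, lin-4, miR-276, miR-192 and miR-16 had a guide majority in both libraries and the other 13 did not. No minimum of reads was set here. Some of these 13 held few arm-labelled reads, such as miR-122 (31 and 23), miR-451 (39 and 45) and miR-486 (37 and 121). Entries with no arm in their name were left out. The pooled shares therefore do not exclude animal RNA for any single family. Among conserved plant families the guide arm held the majority in both libraries in only 6 of 21, so a guide minority is not particular to animal-named families. Loose matching of fragments of other RNA remains a candidate explanation, since 94.7% and 97.5% of the 530 virus-named entries had a read, at least 1.43 times the share of animal-named entries. No biological difference between groups was tested, since the design holds 1 group, and without entry sequences or read lengths the origin of these fragments stays open.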

How the results depend on the processing

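The restriction to families with at least 10 entries, the highest-entry form of the detection test and the lists without their top member were chosen after the data were seen. With 2 libraries, leaving out 1 always moves a mean by less than its SD, so this shows a range but no stability: plant-named share 18.2 to 20.3%, miR165/miR166 14.6 to 16.9%, top 10 families 46.7 to 54.1%, lists for transcription factors 19.8 to 26.2%, nutrients 4.14 to 5.83%, disease resistance 3.52 to 4.19% and small RNA pathway 0.208 to 0.513%, 3p share of miR165/miR166 68.2 to 77.2%, animal markers 1.66 to 2.18%, suspect entries 0.234 to 0.802%. The number of families detected is a count and not a mean. It was 1271 with prep7 left out and 1591 with prep3 left out, both above 1214, because only 1 library then had to reach 10 reads. Per all miRBase reads, which only changes the denominator, miR165/miR166 held 3.05%, the top 10 families 9.76%, and the transcription factor, small RNA pathway, nutrient and disease resistance lists 4.47, 0.0711, 0.971 and 0.740%. With the highest entry in place of the sum, the values were 1.16% and 30.1%, and 2.24, 0.112, 2.24 and 1.47% for the lists. The first place of miR165/miR166 therefore rests on summing its entries, as miR10407 then held 6.57%. Left unmerged, entries named miR166 held 9.98%. Entries of both names were among the 11 with near-equal counts, so the names may not separate miR165 from miR166. Without their top member the transcription factor, nutrient and disease resistance lists held 7.27, 0.417 and 0.267%, and the small RNA pathway list 0.181%, a change within its SD. Families detected were 2379, 1874 and 390 at minimums of 1, 3 and 100 reads. The odds ratio of conserved families was 3.12 (Fisher's exact p = 0.419) among families with at least 10 entries, where fewer families enter. Other alternatives with a finite value gave 22.1 to 58.2, with 36.2 when prep7 was left out. With a minimum of 1 or 3 reads, or with prep3 left out, all 28 conserved families were detected and the ratio has no finite value (Fisher's exact p = 0.00575, 3.87e-06 and 4.06e-08). A minimum of 100 reads left 320 families differing between the libraries, as fewer were tested, and other settings gave 569 to 775. Pearson's r was 0.824 with a pseudocount of 0.1. Of the single families, 18 of 19 moved by at least 1 SD of the libraries per all miRBase reads. With the highest entry 5 of 19 moved, but the 8 single-entry families among them could not. Only 11 of the 19 had values that changed at all there. None of the 19 moved with TMM scaling. Unmerging could not change their values, since none of them is a merged family. A minimum of 1000 arm-labelled reads could not change the arm shares of the 7 families concerned, which all met it already. No family moved without suspect entries either, but the suspect plant families held only 1.94% of plant-named reads. Leaving them out therefore only rescaled the other families slightly, and miR6478, itself suspect, was not compared. A wide SD hides large changes: miR5514 went from 1.43 to 0.285% per all reads and miR9657 from 1.03 to 0.352% with the highest entry, both within 1 SD. Comparisons between the libraries need both, so none could be left out there. No paired analysis was possible because the series has 1 group. With counting error alone, depth limits small changes: the simulated test called 24.0% of 1.25-fold changes. The simulation held no spread between libraries, so it does not show how often such calls are right here.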

Other observations

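The tests on matched random lists, single-entry families, guide arms, calls kept and the shift of conserved families were chosen after counts had been seen, while TMM scaling and the minimum of 100 reads that they use were planned. Single Arabidopsis entries, picked after their values were seen, differed within miR165/miR166. The entry ath-miR165a-3p held 8678 reads in prep3 and 11245 in prep7, while ath-miR166a-3p held 18 and 12. Of other families, ath-miR156a-5p held 1 and 0 reads, ath-miR172a 0 and 2, ath-miR167a-5p 0 and 1, ath-miR168a-5p 2 and 2, and ath-miR408-3p 0 and 0. A low count of 1 entry does not show that a family is absent, since its reads can fall on other entries. Over both arms, miR156/miR157 held 2746 and 3212 reads on 476 entries, and miR167 1028 and 1144 on 244.

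Plant-named families hold reads, and the level of many of them may be background of the kind seen on animal-named entries. The median percentile of the conserved list, 71.3, lay within the range of matched animal-named lists, and single-entry plant-named families were detected less often than animal-named ones (odds ratio 0.598). The median weighs families and not reads, so it says little about the most abundant families. Of the 28 in the list, 5 lay above the 95th percentile, and this number was not compared with the random lists. For miR165/miR166, the highest of the list with 3.05% of all reads, background alone cannot be told apart from a level of its own: 28.4% of the matched random lists had a highest member with as many reads, but each of these drew miR-9, the 1 such animal-named family, and the median highest member held 0.910%. Mature guide strands remain a candidate explanation for most arm-labelled reads of 21 conserved families, since the guide arm held 65.9% and 70.3% of them against 51.1% of the entries, but without miR165/miR166 and miR482 it held 43.6% and 31.6%. No biological difference between groups was tested, since the design holds 1 group.

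Detected families differ between the libraries, and the tables argue against a single shift of the scale: of the 691 families called, 79.9% were still called in the same direction with TMM scaling and 5 in the opposite one. TMM lowered all ratios alike, so the 213 families lower in prep7 had little room to be lost, and the 478 higher ones carried the test. With TMM, families were still called in both directions, 339 higher and 318 lower. Whether conserved and other families shifted alike stays open, with p on both sides of 0.05. Their median log2 ratios were -0.15 over 27 and 0.30 over 1187 families (two-sided permutation p = 0.0483), and -0.15 over 25 and 0.18 over 365 with at least 100 reads in both libraries (permutation p = 0.120). The column names give each library its own preparation number, so preparation, and the sucrose band if it differed, is confounded with library and stays open.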
